A study of Homo sapiens with 16 samples.

How the data were processed

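RNA was measured by poly(A)-selected, paired-end Illumina sequencing in 16 libraries, 4 wells for each of 4 conditions. The cells were MCF10DCIS.com, a premalignant human breast line derived from MCF10A that grows as lesions resembling ductal carcinoma in situ. Per the labels' protocols, a single clone lacking PCSK5 was given back a V5-tagged PCSK5 allele under a tetracycline-regulated promoter, and each allele (wildtype, M452I or T288P) is represented by 1 polyclonal line. The cultures were grown in 3 dimensions on matrigel, received 1 µg/ml doxycycline from day 4, and were harvested on day 8. The fourth condition was the T288P line with 250 ng/ml recombinant GDF11 throughout.

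The deposited table holds whole-number counts per gene for each library, not normalized, as made by the authors. Per the submitters' processing notes, HISAT2 (version not given) and StringTie 2.2.1 were used with genome build GRCh38. The step that produced counts per gene, the annotation release and the strand setting are not given in the sources used here. Counts of 1 and of 2 were about equally frequent in every library, so the 2 mates of a read pair may have been counted separately, and the counts may overstate the number of fragments. Each column name matched the title of 1 library, and 0 columns of values were left unused. The table held 78894 genes, 42760 of them with a symbol, and 0 of its lines lacked a gene name. In all, 39998 genes had no count in any library.

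Gene symbols and identifiers were taken from the deposited table. Coordinates are those of GENCODE release 29 on GRCh38, which covered 15639 (93.1%) of the 16790 genes tested. Without a known strand setting, reads of overlapping genes cannot be assigned. Of the 97 genes named here, SMPD4BP included, 16 share exon bases with another tested gene on the opposite strand and 5 with one on the same strand, for CD68 over 20% of its exon bases. Members of families of near-identical genes (small proline-rich proteins, histones, SMPD4BP) can also share reads, and their levels are uncertain for that reason.

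Tests ran in R 4.3.3. The main test was edgeR 4.0.16 with TMM normalization, filterByExpr (minimum count 10), robust dispersion estimates and the quasi-likelihood F test. All 16 libraries entered a single model without a covariate, so that all groups shared the estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the 16790 genes, and a gene was called at an adjusted p under 0.05. Genes that passed the filter held 99.89% to 99.95% of the counts of a library. Log2 fold changes come from that model, and their standard error (SE) was computed as the absolute log2 fold change divided by the square root of F. Levels are CPM, that is, counts per M counts of a library, scaled with the TMM factors, as mean ± SD of 4 wells.

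M452I, T288P and T288P with GDF11 were compared with the wildtype allele or with untreated T288P. The main comparisons were M452I against WT, T288P against WT, and T288P with GDF11 against T288P. The secondary comparisons were M452I against T288P and T288P with GDF11 against WT. In addition, 30 gene lists (signalling targets, cell states, stress and metabolic pathways, other cell types and RNA quality) were tested with camera (limma 3.58.1, correlation between genes preset at 0.01) on voom values. Lists with at least 5 measured members were tested and adjusted by Benjamini-Hochberg over the 29 such lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, 1 way, and does not compare them with other genes.

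The groups, lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took PCSK5 and GDF11 in every comparison. It then took the 7 called genes with the highest and the 7 with the lowest log2 fold change of each main comparison, 4 and 4 of each secondary comparison, among genes with a symbol that are not annotated as pseudogenes, readthrough or clone-based entries, with a mean of at least 3 CPM in the higher group and no overlap between the 4 and 4 values. Up to 3 called members with the smallest adjusted p were named for each list that passed or had at least 3 called members. SMAD7, SKIL, PMEPA1, up to 6 genes of each overlap, and the markers CDH1, KRT5, KRT14, KRT8, VIM and MKI67 were added regardless of the test. SMPD4BP, annotated as a transcribed pseudogene, lies outside the rule for that reason and was named after its values were seen. Some genes that the rule takes are not reported here.

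Alternatives were DESeq2 1.42.0, limma-voom, RLE normalization, no low-count filter, a stricter filter (at least 50 counts in 4 libraries), a model of only the 2 groups compared, the replicate number as a block, a fold change of at least 2, and leaving out each library in turn. Added after seeing the data were fits without the 2 outlying libraries, with the ribosomal protein share of counts as a covariate, on the 15624 genes with a known transcript length and GC content, on those genes with each library's trends in both removed, and with counts thinned to the smallest library. Overlaps of calls between comparisons that share libraries were set beside 20 simulations of unchanged groups and beside splits of the shared libraries.

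The gene calls, the list tests (on 1 list) and the position of a group between WT and T288P were tested on simulated counts first. The other steps were not tested in this way. Simulated genes were drawn independently of each other, without differences shared by the genes of a well, so false calls may be more frequent in the real data. For T288P with GDF11 against T288P, with 16790 genes of which 50 were changed at each fold, edgeR recovered 32% of genes simulated at 1.5-fold, 54% at 2-fold, 76% at 3-fold and 76% at 4-fold, with 4 false calls among 123. For the same comparison and genes DESeq2 recovered 42%, 66%, 84% and 80%, with 30 false calls among 166. In M452I against WT, simulated without change over those 16790 genes, edgeR made 0 calls, limma-voom 0 and DESeq2 6. Library totals ran from 28.5 to 50.8 M counts, and the common biological coefficient of variation was 0.237. The chi-square per gene between libraries of a group was 12.7 to 153.8, so no library repeats another. Error ranges from counting alone are not given. P-values measure the spread between wells, which share a clone and a line, and do not cover a difference between independently made lines.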

Results

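Transcript levels were measured in MCF10DCIS.com breast cells that lack their own functional PCSK5 and carry an inducible PCSK5 allele. PCSK5 encodes a proprotein convertase, an enzyme that cleaves precursors of secreted proteins, among them the precursor of GDF11. GDF11 is a ligand of the TGF-beta family that signals through SMAD2 and SMAD3. The 4 conditions, each with 4 wells, were the wildtype allele (WT), the M452I allele, the T288P allele, and T288P with 250 ng/ml mature GDF11 (T288P+GDF11). The library totals averaged 36.5 M counts (SD 6.66, n = 16) and ranged from 28.5 to 50.8 M, and 21777 to 25335 genes were detected per library. The mean was 38.3 M in WT, 38.25 in M452I, 34.72 in T288P and 34.72 in T288P+GDF11. Correlations of log2 CPM between libraries were 0.9581 to 0.9774 within groups and 0.9496 to 0.9784 between groups.

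The first principal component of log2 CPM held 27.1% of the variance and the second 9%. The T288P+GDF11 wells scored 44.1 to 63.6 on the first component. Among untreated wells, 2 stood apart from their groups. M452I replicate 4 scored 37.5 against -44.7 to -32.9 for the other M452I wells, and T288P replicate 1 scored -43 against 2.1 to 8.8. M452I replicate 4 also had the lowest share of ribosomal protein counts, 8.63% against 11.8% to 12.1% in the other M452I wells. In WT that share was 10.05% ± 0.733 (SD, n = 4).

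**Figure D1:**
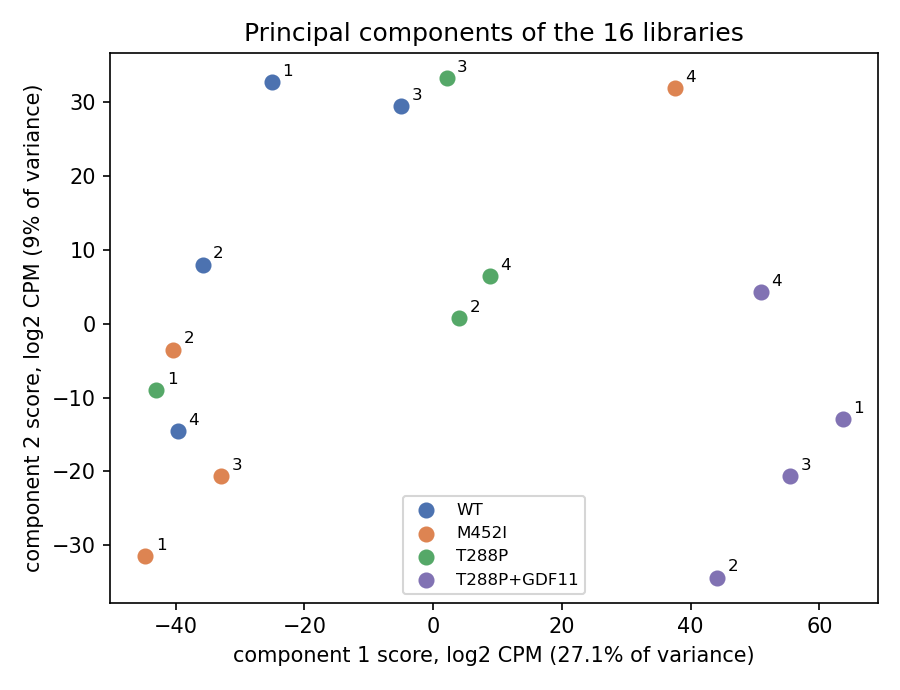
Scores of the 16 libraries on the first (27.1% of variance) and second (9%) principal components of log2 CPM, coloured by condition, with the replicate number beside each point. The 4 T288P+GDF11 wells score 44.1 to 63.6 on component 1, while M452I replicate 4 (37.5) and T288P replicate 1 (-43) lie away from the other wells of their conditions.

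PCSK5 (ENSG00000099139; chromosome 9, 75890644 to 76362339) was transcribed at 45.4 ± 12 CPM in WT, 39.5 ± 19.3 in M452I, 37.7 ± 13.5 in T288P and 40.8 ± 10.7 in T288P+GDF11 (SD, n = 4 each). No comparison called it, and the log2 fold change of M452I against WT was -0.20 (SE 0.33; edgeR adjusted p = 0.925) and that of T288P against WT -0.27 (SE 0.33; edgeR adjusted p = 0.894). The counts do not separate the introduced allele from the transcript of the edited locus, and they carry no information on protein activity. The cells' own GDF11 transcript (ENSG00000135414; chromosome 12, 55743280 to 55757278) stood at 5.81 ± 1.63 CPM in WT, 5.76 ± 1.06 in M452I, 5.75 ± 1.07 in T288P and 7.05 ± 0.738 in T288P+GDF11 (SD, n = 4 each), and no comparison called it.

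The comparison of M452I with WT asks what the M452I substitution, which the series calls a hypomorph, changes in these cultures. PADI2 (ENSG00000117115; chromosome 1, 17066761 to 17119435), an enzyme that converts arginine to citrulline in proteins, fell from 15.8 ± 2.31 CPM in WT to 7.74 ± 0.909 in M452I, a 2.04-fold lower level (log2 fold change -1.03, SE 0.14; edgeR adjusted p = 0.00505). TGFBI (ENSG00000120708; chromosome 5, 136028895 to 136063818), a matrix protein induced by TGF-beta, rose from 75.8 ± 5.26 to 119 ± 13.7 CPM (log2 fold change 0.65, SE 0.09; edgeR adjusted p = 0.00505). The inflammatory cytokine IL1B (ENSG00000125538; chromosome 2, 112829751 to 112836903) rose from 72 ± 6.93 to 117 ± 20.4 CPM (log2 fold change 0.70, SE 0.12; edgeR adjusted p = 0.049988). The 4 M452I wells did not overlap the 4 WT wells for any of these genes. The other call was the pseudogene SMPD4BP (ENSG00000293311), singled out after its values were seen, which fell from 8.76 ± 1.54 to 3.86 ± 0.73 CPM (log2 fold change -1.18, SE 0.15; edgeR adjusted p = 0.00505). A second entry of the same symbol moved the other way, from 0.266 ± 0.38 to 3.83 ± 2.2 CPM. These 4 genes, 2 higher and 2 lower, were all that edgeR called among 16790, while 1058 had an unadjusted p under 0.05 where 840 would by chance. The epithelial cadherin CDH1 was 413 ± 34.4 CPM in WT and 345 ± 26.2 in M452I, and the proliferation marker MKI67 73.1 ± 9.02 and 54.9 ± 8.2, neither past the test (edgeR adjusted p = 0.727 and 0.73).

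The count rested on single wells. It was 1 without WT replicate 2, which ended the calls of PADI2 (edgeR adjusted p = 0.0575), TGFBI and IL1B, 2 without WT replicate 4, which ended those of TGFBI and IL1B, and 9 without M452I replicate 4, and IL1B was lost without any 1 well of either group except M452I replicate 4 (highest edgeR adjusted p = 0.319). DESeq2 called 28 genes in M452I against WT, an edgeR fit of only the M452I and WT wells 0 (899 with an unadjusted p under 0.05), and RLE normalization 1 higher and 2 lower. On the 15624 genes with a known length and GC content, which leave SMPD4BP untested, edgeR called PADI2 and TGFBI. Removal of length and GC trends on those genes left TGFBI and ended the call of PADI2, whose log2 fold change went from -1.03 (SE 0.14) to -0.98 (SE 0.17; edgeR adjusted p = 0.0991), a slightly smaller change with a wider spread. Without both M452I replicate 4 and T288P replicate 1, a choice made after seeing the data, edgeR called 654 genes, 510 higher and 144 lower in M452I.

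Across the gene lists, 14 of 29 passed camera with its preset correlation in M452I against WT, 3 towards higher and 11 towards lower values, and 0 passed with an estimated correlation or by fry. Without WT replicate 1 the number that passed camera was 9. The shifts were small. The cytosolic ribosomal protein genes, the protein part of the translation machinery, had a median log2 fold change of 0.211, with 0 of 46 called over all genes and 0 adjusted over the list alone (camera adjusted p = 8.6e-07; adjusted p = 0.547 with an estimated correlation). Nuclear genes of oxidative phosphorylation, which encode respiratory chain subunits, had a median of 0.159, with 0 of 32 called either way (camera adjusted p = 5.08e-05; adjusted p = 0.547 with an estimated correlation). Without the 2 outlying wells, 44 of the 46 ribosomal protein genes and 13 of the 32 respiratory genes were called higher in M452I. In M452I replicate 4, 1 of the wells left out, these lists lay at -0.82 and -0.61 log2 units from the other M452I wells. The wells were chosen after seeing the data, so these counts follow in part from that choice. SMAD2/3 targets had 1 called member of 33, TGFBI, and a median of -0.083 (camera adjusted p = 0.047; adjusted p = 0.547 with an estimated correlation). Junction genes had a median of -0.106 with 0 of 29 called, or adjusted over the list alone, 0 (camera adjusted p = 0.00011; adjusted p = 0.547 with an estimated correlation).

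The T288P allele was compared with WT as the other mutant allele of the design. PADI2 fell from 15.8 ± 2.31 CPM to 6.53 ± 1.05, 2.42-fold lower (log2 fold change -1.27, SE 0.14; edgeR adjusted p = 0.000736), and the neighbouring PADI1 (ENSG00000142623; chromosome 1, 17205126 to 17246005) from 5.73 ± 0.767 to 2.41 ± 0.315, 2.38-fold lower (log2 fold change -1.25, SE 0.22). PPL (periplakin, a protein of desmosomes and the cornified envelope) fell from 79 ± 7.82 to 50.4 ± 8.35 CPM, the non-muscle myosin MYH14 from 25.7 ± 2.69 to 15 ± 2.44, and the carboxypeptidase inhibitor LXN from 14.9 ± 1.18 to 8.74 ± 0.651. IL1B rose from 72 ± 6.93 to 122 ± 16.4 CPM (log2 fold change 0.76, SE 0.12; edgeR adjusted p = 0.0329) and TGFBI from 75.8 ± 5.26 to 110 ± 9.46 (log2 fold change 0.54, SE 0.09). For PADI1, PPL, MYH14, LXN and TGFBI the edgeR adjusted p was 0.0386. All 4 T288P wells lay outside the range of the WT wells for these 7 genes, 2 higher and 5 lower, which were the only calls by edgeR among 16790 genes (1425 with an unadjusted p under 0.05). CDH1 was 341 ± 12.7 CPM in T288P (edgeR adjusted p = 0.37), and KRT8, a keratin of luminal cells, 477 ± 154 against 687 ± 121 in WT (edgeR adjusted p = 0.604).

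**Figure D2:**
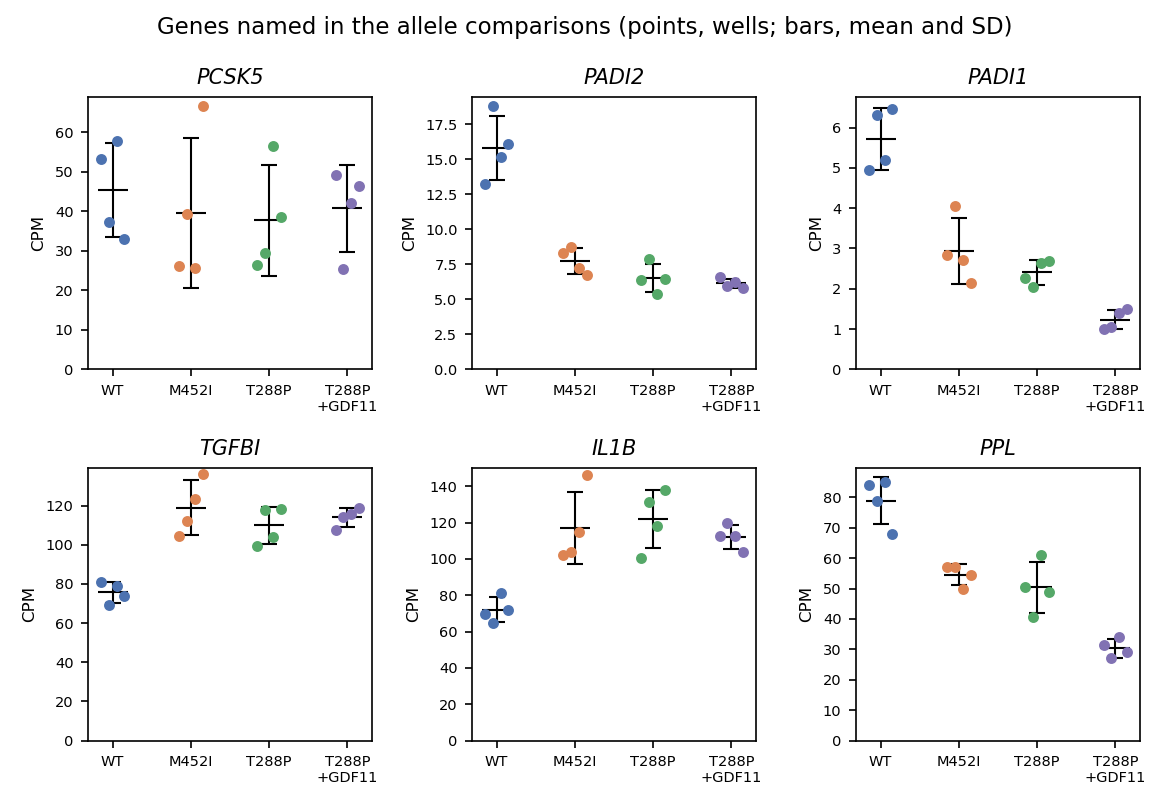
CPM of PCSK5, PADI2, PADI1, TGFBI, IL1B and PPL in each well by condition, with points for wells and bars for the mean and SD of 4 wells. PADI2 is 15.8 CPM in WT against 7.74 in M452I and 6.53 in T288P, while the PCSK5 wells of all conditions overlap.

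PADI2 was the only 1 of the 7 genes called against WT whichever T288P or WT well was left out. The T288P count was 1 without WT replicate 1, WT replicate 2, T288P replicate 2 or T288P replicate 4, 2 without T288P replicate 3, 3 without WT replicate 3 or WT replicate 4, and 16 without T288P replicate 1, and PADI1 and LXN were lost whichever of the 8 wells was left out (highest edgeR adjusted p = 0.289 for PADI1). The replicate number as a block left 1 call, PADI2, and ended the other 6, with log2 fold changes close to those above (0.75 for IL1B, -1.25 for PADI1). DESeq2 called 80 genes in T288P against WT, edgeR with the ribosomal protein share as a covariate 299, the fit without a low-count filter 11, and edgeR without both outlying wells 701, of which 294 were higher and 407 lower.

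Of 29 lists, 8 passed camera in T288P against WT, all towards lower values, and 0 passed with an estimated correlation or by fry. The number that passed camera was 2 without T288P replicate 2, 4 without WT replicate 1 or WT replicate 3, and 5 without T288P replicate 4. The luminal list, keratins and transcription factors of luminal breast cells, had a median log2 fold change of -0.157 and 0 of 12 members called, with 3 lower when adjusted over the list alone (camera adjusted p = 0.000386; adjusted p = 0.295 with an estimated correlation). Junction genes had a median of -0.136 and 0 of 29 called, with 0 adjusted over the list alone (camera adjusted p = 0.000105; adjusted p = 0.679 with an estimated correlation). Without the 2 outlying wells, 6 junction genes and 3 luminal genes were called lower. In T288P replicate 1, 1 of the wells left out, the junction list lay 0.06 log2 units above the other T288P wells and the luminal list 0.25. These counts may therefore depend in part on the choice of wells. SMAD2/3 targets had 1 called member (TGFBI) of 33 over all genes and 1 adjusted over the list alone, and did not pass (camera adjusted p = 0.326).

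The alleles were also compared directly. M452I and T288P differed in 1 gene by edgeR, SMPD4BP, which was 3.86 ± 0.73 CPM in M452I and 8.78 ± 0.11 in T288P (log2 fold change -1.18, SE 0.15; edgeR adjusted p = 0.00513). PADI2 (7.74 ± 0.909 and 6.53 ± 1.05 CPM), TGFBI (119 ± 13.7 and 110 ± 9.46) and IL1B (117 ± 20.4 and 122 ± 16.4) were not called between the alleles, and fewer genes had an unadjusted p under 0.05 (366) than the 840 of chance. DESeq2 called 6 genes and limma-voom 1 between M452I and T288P. Without both outlying wells edgeR called 2448, 1538 higher and 910 lower in M452I, among them 46 of 46 ribosomal protein genes and 17 of 28 unfolded protein response genes, all higher. Those wells were chosen after seeing the data, and both lists ran the other way in them. From the other wells of the condition, the ribosomal list lay at -0.82 log2 units in M452I replicate 4 and 0.36 in T288P replicate 1. The unfolded protein response list lay at -0.65 and 0.37. The counts of both lists therefore follow in part from the choice of wells. In all 16 libraries the camera test of the ribosomal list gave a median log2 fold change of 0.19 and an adjusted p = 6e-08 (adjusted p = 0.895 with an estimated correlation), with 0 of 46 called.

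PADI2, TGFBI and IL1B were called in the same direction in both alleles against WT, 3 genes where independent lists would share 0.000834. PADI1, PPL, MYH14 and LXN, called only in T288P, were also lower in every M452I well than in every WT well. PADI1 ran from 2.14 to 4.06 CPM in M452I and 4.96 to 6.47 in WT, and PPL from 49.8 to 57.26 and 68.03 to 85.05. MYH14 ran from 14.54 to 18.12 and 22.56 to 28.64, and LXN from 8.22 to 10.81 and 13.16 to 15.88. The comparisons use the same WT wells, and simulated groups without an effect shared 0, a value that decides nothing, since each simulated comparison held at most 1 call and both held calls in only 1 of 20 simulations. DESeq2 gave 20 shared genes. Leaving out 1 WT, M452I or T288P library gave 0 to 3: it was 0 without WT replicate 2, 2 without M452I replicate 1, 3 without M452I replicate 4 or T288P replicate 1, and 1 without any other well of these conditions. The correlation of the fold changes across 16790 genes, which are not independent replicates, was 0.556, against 0.498 in simulations without an effect. The covariance was 0.12 against 0.1061 simulated. With the WT wells split between the comparisons the correlation was 0.065 (range -0.028 to 0.117 over 6 splits).

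GDF11 was given to the T288P line to supply the mature ligand from outside. With it the fibronectin gene FN1 rose from 69.4 ± 18.7 to 293 ± 32.5 CPM (4.23-fold; SD, n = 4 each) and the integrin gene ITGB6 3.03-fold. Vimentin (VIM), an intermediate filament of mesenchymal cells, rose 2.02-fold and CDH1 fell to a 1.47-fold lower level, while SPRR2A, a small proline-rich protein of the cornified envelope, fell from 40.8 ± 10.8 to 7.95 ± 1.06 CPM, a 5.12-fold lower level. In total 2174 of 16790 genes were called by edgeR, 851 higher and 1323 lower (39.1% higher), and 410 by at least 2-fold, 259 higher and 151 lower. A fit of only the T288P and T288P+GDF11 wells called 1279 higher and 1218 lower, so the excess of lower calls depends on the model.

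Among the called genes of the naming rule, with a mean of at least 3 CPM in the higher group and no overlap between wells, the highest were SCG5, a chaperone of the convertase PCSK2 (log2 fold change 4.51, SE 0.96, from 0.32 ± 0.577 to 6.84 ± 2.15 CPM), and ZBED2, a zinc finger transcription factor (3.35, SE 0.71). After them came the metalloprotease MMP10 (2.94, SE 0.48), the sulfate transporter SLC26A2 (2.55, SE 0.55), the receptor MRGPRX3 (2.51, SE 0.39), DCDC2C (2.37, SE 0.49) and the netrin receptor UNC5C (2.24, SE 0.56). Among the lowest were SPRR2E (-2.43, SE 0.31), SPRR2A (-2.36, SE 0.31), the calcium-binding protein S100A8 (-2.34, SE 0.39), and collagen VI chain COL6A1 (-2.28, SE 0.33). Heme oxygenase HMOX1 (-2.17, SE 0.54) and the adhesion molecule CEACAM5 (-2.06, SE 0.15) followed. EdgeR adjusted p-values ran from 2.38e-07 for CEACAM5 to 0.0211 for HMOX1, and for each gene the groups of 4 wells did not overlap. T288P replicate 1 held 67.6 CPM of HMOX1 against 21.6 to 23.1 in the other T288P wells. The HMOX1 call was lost without T288P replicate 1, T288P+GDF11 replicate 1 or T288P+GDF11 replicate 3 (highest edgeR adjusted p = 0.0771), and that of UNC5C without T288P replicate 1 (edgeR adjusted p = 0.0604).

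**Figure D3:**
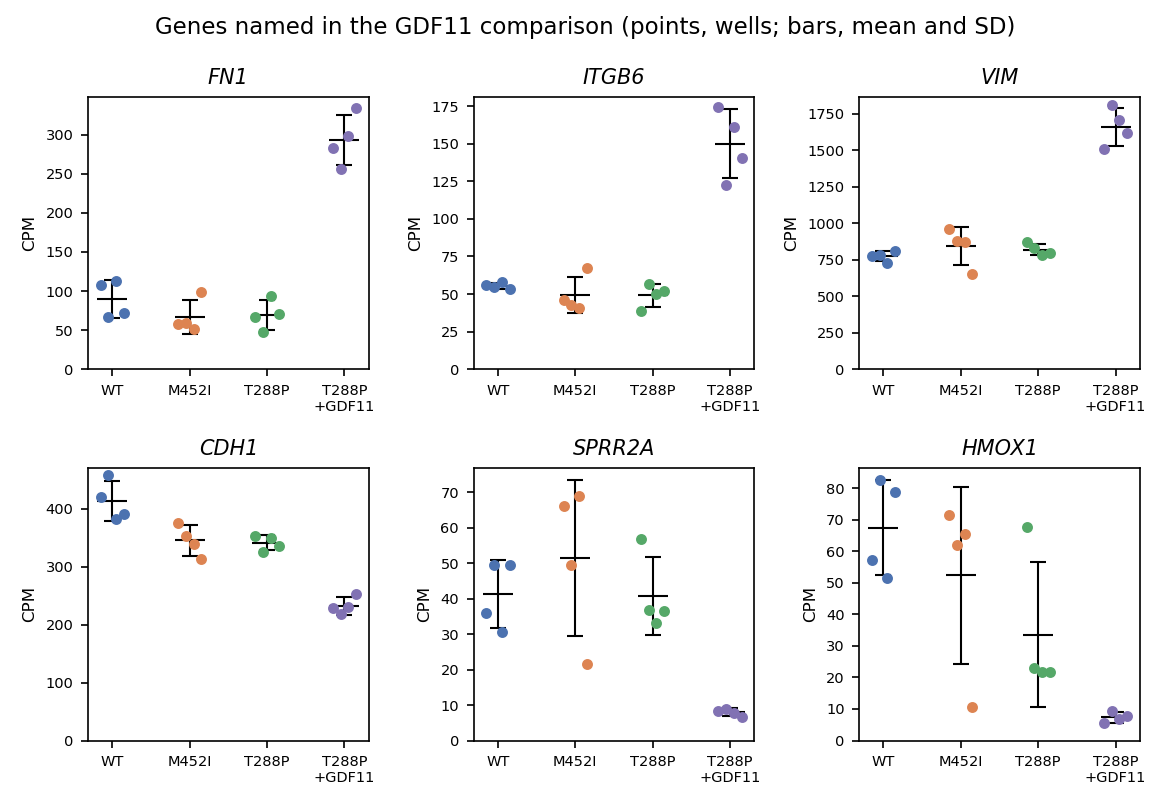
CPM of FN1, ITGB6, VIM, CDH1, SPRR2A and HMOX1 in each well by condition, with points for wells and bars for the mean and SD of 4 wells. FN1 is 69.4 CPM in T288P and 293 with GDF11, SPRR2A 40.8 and 7.95, and M452I replicate 4 and T288P replicate 1 lie apart from their groups for HMOX1.

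SMAD2/3 targets rose as a list with GDF11: 11 of 33 measured members rose, 3 fell and 19 did not pass, or 15 and 5 adjusted over the list alone (median log2 fold change 0.433; camera adjusted p = 2.33e-05; adjusted p = 0.229 with an estimated correlation). ITGB6, an integrin subunit that activates latent TGF-beta, rose from 49.3 ± 7.63 to 150 ± 22.9 CPM (log2 fold change 1.60, SE 0.15; edgeR adjusted p = 5.19e-06). PMEPA1, a feedback inhibitor of the pathway, rose from 79.2 ± 11.8 to 198 ± 6.44 (1.33, SE 0.14; edgeR adjusted p = 2.19e-05), and FN1 rose by 2.08 (SE 0.24; edgeR adjusted p = 7.92e-05). The inhibitors SMAD7 (3.53 ± 0.815 and 4.87 ± 0.317 CPM; edgeR adjusted p = 0.138) and SKIL (93.9 ± 14 and 125 ± 16 CPM; edgeR adjusted p = 0.0752) did not pass. Of 12 BMP SMAD1/5 targets, 3 rose and 1 fell, the same numbers adjusted over the list alone, without passing as a list (camera adjusted p = 0.147; adjusted p = 0.325 with an estimated correlation). ID3 and ID2, inhibitors of differentiation factors, rose 2.31-fold and 1.63-fold. Among 27 ligands, receptors and antagonists of the family, 3 rose and 2 fell, also over the list alone (camera adjusted p = 0.466), and these included a rise of LTBP2, a latent TGF-beta binding protein, to a 2.82-fold higher level and a fall of the activin receptor ACVR1C (-1.29, SE 0.24).

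With GDF11, of 20 mesenchymal genes 5 rose, 2 fell and 13 did not pass, or 6 and 2 adjusted over the list alone (median 0.33; camera adjusted p = 0.000352; adjusted p = 0.162 with an estimated correlation). Examples were VIM, from 820 ± 38.4 to 1660 ± 128 CPM (log2 fold change 1.02, SE 0.11), and SPARC, a matrix glycoprotein, from 14 ± 2.77 to 34.4 ± 6.27 (1.30, SE 0.14), against the fall of COL6A1. Of 29 junction genes 12 fell, 0 rose and 17 did not pass, or 18 and 2 adjusted over the list alone (median -0.288; camera adjusted p = 6.71e-08; adjusted p = 0.162 with an estimated correlation). The tight junction protein OCLN fell from 30.5 ± 4.64 to 13.2 ± 1.92 CPM (-1.21, SE 0.16) and CDH1 from 341 ± 12.7 to 232 ± 14.8 (-0.55, SE 0.08). Without both outlying wells, a choice made after seeing the data, 6 mesenchymal genes rose and 16 junction genes fell. Here and for the lists below, M452I replicate 4 enters this comparison only through the shared spread. Without T288P replicate 1 alone, 1046 genes were called in all instead of 2174.

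Squamous differentiation had the lowest median of the lists tested in this comparison, -1.55 over 22 measured genes. Of these 14 fell and 0 rose, or 15 and 0 adjusted over the list alone (camera adjusted p = 4.71e-10; adjusted p = 0.162 with an estimated correlation). Beside SPRR2E and SPRR2A, SPRR1A fell 3.2-fold and SPRR1B 2.31-fold (edgeR adjusted p = 5.19e-06 and 3.84e-05). Luminal genes fell in 5 of 12 members and rose in 0, or 7 and 0 adjusted over the list alone (median -0.501; camera adjusted p = 0.00364; adjusted p = 0.192 with an estimated correlation). The epithelial transcription factor ELF3 fell from 49.8 ± 12.8 to 17 ± 2.4 CPM, the receptor ERBB3 from 54.6 ± 3.86 to 33.6 ± 4.43, and the pioneer factor FOXA1 from 10.4 ± 0.998 to 6.26 ± 0.646. Basal and myoepithelial genes went both ways, 3 higher and 3 lower of 20, or 6 and 3 adjusted over the list alone, with a median of -0.023, a mean of 0.055 and a test towards higher values (camera adjusted p = 0.52). The laminin chain LAMA3 (1310 ± 271 to 2960 ± 353 CPM, 2.26-fold) rose and the basal keratin KRT5 fell from 2350 ± 179 to 1730 ± 86.4 CPM. LAMA3 also counts among 22 basement membrane genes, of which 4 rose and 2 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.164). KRT14, another basal keratin, was 79.7 ± 18.3 and 69 ± 4.88 CPM, and KRT8 477 ± 154 and 302 ± 30.7, neither past the test (edgeR adjusted p = 0.355 and 0.105). In T288P replicate 1 the squamous list lay 0.51 log2 units above the other T288P wells by its median, and in M452I replicate 4 it lay at -0.54 from the other M452I wells. Without both wells 13 squamous genes fell and 1 rose.

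**Figure D4:**
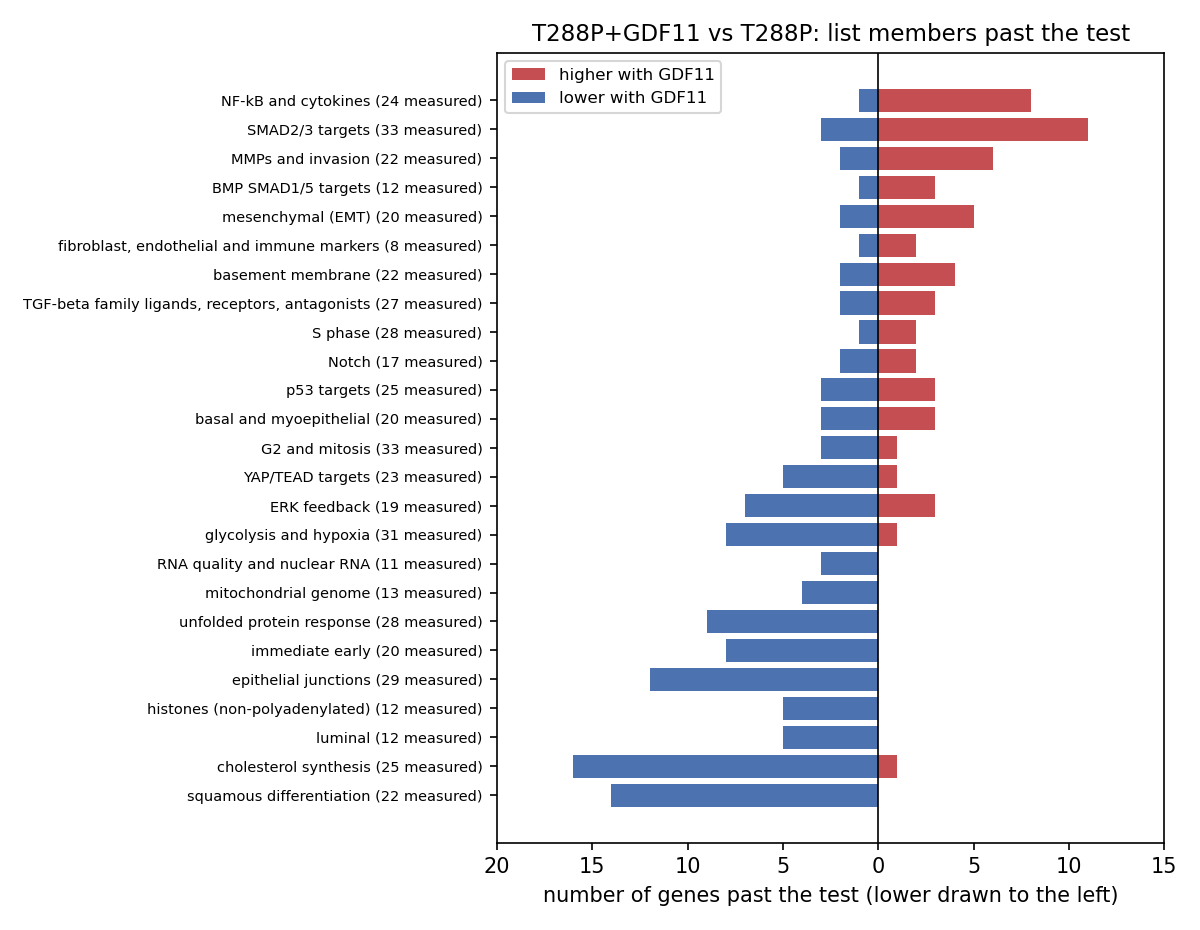
Number of list members past the edgeR test in T288P+GDF11 against T288P, higher with GDF11 to the right and lower to the left, with the number of measured members in parentheses. Squamous differentiation (14 of 22 lower), cholesterol synthesis (16 of 25) and epithelial junctions (12 of 29) lie mostly to the left, SMAD2/3 targets (11 of 33 higher) to the right.

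Some cytokine genes rose with GDF11. Of 24 NF-kB and cytokine genes 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (median 0.277; camera adjusted p = 0.000977; adjusted p = 0.192 with an estimated correlation). The neutrophil chemokines CXCL1 (45.2 ± 9.23 to 105 ± 14.6 CPM, 2.33-fold) and CXCL3 (2.28-fold) and the mitochondrial superoxide dismutase SOD2 (1.67-fold) were among them. IL1B was 122 ± 16.4 CPM in T288P and 112 CPM on average with GDF11. Immediate early genes, the first to respond to growth factors and stress, fell in 8 of 20 members and rose in 0, or 9 and 1 adjusted over the list alone (median -0.305; camera adjusted p = 0.00258; adjusted p = 0.42 with an estimated correlation). NR4A1 fell 2.42-fold, FOSB 1.74-fold and EGR1 1.6-fold. Invasion genes rose in 6 of 22 members and fell in 2, or 11 and 7 adjusted over the list alone (camera adjusted p = 0.00901; adjusted p = 0.41 with an estimated correlation; camera adjusted p = 0.0582 without T288P replicate 2). The protease inhibitor SERPINE2 rose 1.88-fold and the metalloprotease inhibitor TIMP2 fell to a 1.57-fold lower level.

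Cholesterol synthesis fell with GDF11 in 16 of 25 genes, with 1 higher, or 20 and 1 adjusted over the list alone (median -0.504; camera adjusted p = 3.81e-08; adjusted p = 0.325 with an estimated correlation). FDPS, which makes farnesyl diphosphate, fell from 575 ± 68.2 to 369 ± 38.8 CPM. Of 28 unfolded protein response genes 9 fell and 0 rose, or 14 and 0 adjusted over the list alone (median -0.318; camera adjusted p = 8.88e-07; adjusted p = 0.42 with an estimated correlation; fry adjusted p = 0.0573). The endoplasmic reticulum chaperone HSPA5 fell from 2090 ± 663 to 973 ± 114 CPM, the stress factor ATF3 from 92 ± 41.3 to 27.7 ± 5.57, and the phosphatase subunit PPP1R15A from 134 ± 42.3 to 60.1 ± 8.85. These lists also differed between wells of the same condition. The cholesterol list lay 0.38 log2 units above the other T288P wells in T288P replicate 1, and the stress list 0.37. The corresponding values in M452I replicate 4 against the other M452I wells were -0.55 and -0.65. Without both wells 17 cholesterol genes and 12 stress genes fell.

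Some markers of other cell types and of RNA quality moved too. Of 8 measured fibroblast, endothelial and immune markers 2 rose and 1 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.0233; adjusted p = 0.162 with an estimated correlation; camera adjusted p = 0.0519 without T288P replicate 4). The endothelial marker PECAM1 rose from 0.524 ± 0.239 to 1.74 ± 0.668 CPM, so its level stayed low. Of 11 RNA quality and nuclear transcripts 3 fell and 0 rose, or 4 and 0 adjusted over the list alone, and the small nucleolar RNA host gene SNHG3 fell from 61.9 ± 8.54 to 39.9 ± 2.01 CPM (camera adjusted p = 0.0197; adjusted p = 0.42 with an estimated correlation; camera adjusted p = 0.0654 without T288P replicate 1). In M452I replicate 4 that list lay at -0.93 and in T288P replicate 1 at 0.5 log2 units from the other wells of the condition. Ribosomal protein genes had 0 of 46 members called, and 0 adjusted over the list alone, at a median of -0.139 (camera adjusted p = 0.0263; adjusted p = 0.832 with an estimated correlation). This list no longer passed camera without T288P replicate 1 (adjusted p = 0.664), T288P+GDF11 replicate 1 (0.182) or T288P+GDF11 replicate 4 (0.096).

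The number of genes changed by GDF11 in the T288P line moved with single wells, to 1046 without T288P replicate 1, 1223 without T288P+GDF11 replicate 1 and 1220 without T288P+GDF11 replicate 3, and to 1391 without a low-count filter. Without both outlying wells 2361 genes were called, 1911 of them shared with the 2174. In the fit of all 16 libraries 17 of 29 lists passed camera, 0 passed with an estimated correlation and 13 by fry.

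T288P+GDF11 was set against WT to ask what separated the treated mutant line from the wildtype allele. Among genes of at least 3 CPM in the higher group, SCG5 (log2 fold change 4.29, SE 0.93), ZBED2 (3.42, SE 0.71), SLC26A2 (3.36, SE 0.57; 5.64 ± 1.12 to 58.4 ± 20.4 CPM) and MRGPRX3 (3.26, SE 0.41) were higher. HMOX1 (-3.18, SE 0.56; 67.5 ± 15.5 to 7.41 ± 1.69 CPM), COL6A1 (-2.51, SE 0.33) and KIAA0319 (-2.44, SE 0.27) were among the lowest of them. CDH1 was 1.78-fold lower, KRT8 2.27-fold lower, MKI67 1.65-fold lower and VIM 2.14-fold higher than in WT (edgeR adjusted p = 4.24e-06, 0.00342, 0.000897 and 3.02e-06). edgeR called 4846 genes, 2319 higher and 2527 lower, and 1109 by at least 2-fold. All 11 of these genes stayed called whichever T288P+GDF11 or WT well was left out. Removal of length and GC trends moved the split to 1838 higher and 3128 lower, where the same 15624 genes gave 2287 and 2498 without it, and a fit of only the wells compared to 3017 higher and 2944 lower.

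Of 29 lists 13 passed camera against WT, 0 with an estimated correlation and 17 by fry. Junction genes fell in 19 of 29 and rose in 0, or 21 and 1 adjusted over the list alone (camera adjusted p = 2.46e-08; adjusted p = 0.195 with an estimated correlation), and luminal genes in 7 of 12, the same adjusted over the list alone (camera adjusted p = 0.000392; adjusted p = 0.195 with an estimated correlation). Squamous genes fell in 15 of 22 and rose in 0, or 18 and 1 adjusted over the list alone (camera adjusted p = 2.22e-07; adjusted p = 0.312 with an estimated correlation). SMAD2/3 targets rose in 11 of 33 and fell in 4, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.00317; adjusted p = 0.386 with an estimated correlation).

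Whether GDF11 moved the T288P line back towards WT was tested on genes called in both T288P against WT and T288P+GDF11 against T288P. By edgeR 0 genes were called in opposite directions and 3 in the same direction, where independent lists would give 0.411 in opposite directions. No expected number was computed for the same direction. With only 7 genes called in T288P against WT, this count cannot decide the question. Simulated groups without an effect shared 0, which decides nothing, since their T288P+GDF11 comparison held 0 calls. DESeq2 gave 13 in opposite directions, and leaving out T288P replicate 1 gave 2 by edgeR. Of the genes lower in T288P than in WT, PPL went on to 30.4 CPM on average with GDF11 and PADI1 to 1.23, against 50.4 ± 8.35 and 2.41 ± 0.315 without it, and MYH14 to 7.65 against 15 ± 2.44. PADI2 stood at 6.14 CPM with GDF11 against 6.53 ± 1.05 (edgeR adjusted p = 0.712), and LXN at 11 against 8.74 ± 0.651, towards the 14.9 of WT but not called (edgeR adjusted p = 0.0971). For the genes higher in T288P than in WT, wells with and without GDF11 overlapped. The SMAD2/3 target TGFBI ran from 107.46 to 118.96 CPM with GDF11 and from 99.6 to 118.15 without it. IL1B ran from 103.96 to 119.84 and from 100.65 to 137.79. The correlation of the fold changes across genes was -0.154, against -0.501 in simulations in which the shared T288P wells are the only link. The covariance was -0.0471 against -0.1072. With the T288P wells split the correlation was 0.19 (range 0.057 to 0.335). The position of M452I between WT (0) and T288P (1) could not be determined. Of 36 ways to divide the WT and T288P wells 31 gave any gene, with a median of 3 genes, and the ratio ran from -0.771 to 129.149 with a mean of 5.343 (3.382 without M452I replicate 4) and a median of 1.433 (0.767). With the 100 genes of smallest p in all 36 ways it still ran from -3.035 to 48.166, with a mean of 2.073 and a median of 0.9. The mean was 1.124 at a fold of at least 2, 1.807 with the stricter filter and 2.063 with RLE. T288P+GDF11 could not be placed on this scale either: the mean was 22.541 and the median 2.656, with means of 0.309 at a fold of at least 2, 7.703 with the stricter filter, 7.257 with RLE and 8.629 with the 100 genes.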

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

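The removal of length and GC trends, the fit of genes of known length, the sum of both SMPD4BP entries, the fit without both outlying wells and those with the ribosomal share or thinned counts were tests chosen only after the result was seen or after the data were seen.

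M452I replicate 4 stood apart from the other 3 wells of its line in 15 quantities. Higher there were the sulfate transporter SLC26A2 (24.7 CPM against 5 to 5.34), the transcription factor ZBED2 (7.24 against 0.64 to 1.75), fibronectin FN1 (99 against 51.5 to 59.2), the laminin chain LAMA3 (1660 against 1072 to 1161) and MKI67 (67.1 against 49.6 to 52.4). Lower were HMOX1 (10.7 against 61.9 to 71.4), the chaperone HSPA5 (1133 against 2671 to 2807), KRT8 (277 against 667 to 742), the lysosomal protein CD68 (117 against 211 to 230), the receptor EPHA2 (265 against 381 to 392), FOSB (13.4 against 17.5 to 18.1) and RRM2, a subunit of ribonucleotide reductase (59.8 against 92.5 to 96.1). The ribosomal protein share (8.63% against 11.8% to 12.1%), the share of the 10 most abundant genes (9.2% against 10.9% to 11%) and the TMM factor (1.12 against 0.887 to 0.899) stood apart too.

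T288P replicate 1 stood apart in 8 quantities, with HMOX1 and KRT8 the other way. Higher than in the other T288P wells were HMOX1 (67.6 CPM against 21.6 to 23.1), KRT8 (708 against 389 to 406), PPP1R15A (197 against 108 to 120), SPRR2A (56.8 against 33.2 to 36.7), the mitotic activator CDC20 (131 against 63.5 to 71.9) and KCNQ1OT1, a nuclear RNA (10.8 against 7.43 to 7.91). Lower were the chemokine CXCL1 (31.5 against 48 to 51) and the replication factor MCM3 (4.47 against 8.42 to 8.99).

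Other wells stood apart in fewer genes. T288P replicate 3 was higher for AMOTL2 (42.5 CPM against 33 to 34.5), CEACAM5 (31.3 against 22.7 to 24.1), KDR (0.24 against 0 to 0.04) and SCG5 (1.18 against 0 to 0.1). T288P+GDF11 replicate 4 was higher for the hexokinase HK2 (157 against 127 to 130) and lower for ID3 (16.5 against 23.4 to 23.6), PLK2 (11.6 against 14 to 14.1) and SMAD7 (4.4 against 4.97 to 5.08). T288P+GDF11 replicate 1 was higher for PECAM1 (2.74 against 1.33 to 1.44), SMPD4BP (8.24 against 7.77 to 7.84) and the share of mitochondrial counts (4.88% against 4.39% to 4.4%). GDF11 was lower in T288P+GDF11 replicate 3 (5.95 against 7.33 to 7.55). SMPD4BP was higher in M452I replicate 2 (4.95 against 3.39 to 3.64). In all, 36 of 412 groups of 4 wells (97 genes and 6 library measures) had a well this far from the others, where chance gives about 1 in 20, or 21. The genes are not independent of each other.

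The axis that separates WT and M452I wells within their groups held 31.5% of that variance over 8 libraries, and across 16790 genes it correlated with the GDF11 log2 fold change at a Spearman rho of 0.43, although no treated well defined it. M452I replicate 4 carries most of that axis, with a score of 76.2 within its group against -37.3 to 28.5 for the other 7 wells, and its label is in doubt. With length and GC trends removed 2455 genes were called instead of 2174 (1934 shared of the 2123 with a known length). This argues against those trends as the source of the GDF11 calls as a whole. Without both outlying wells 2361 genes were called (1911 shared), but M452I replicate 4 enters this comparison only through the shared spread. Without T288P replicate 1 alone, which leaves fewer wells, 1046 were called (1030 shared), so the part played by that well stays open. The ribosomal protein share as a covariate gave 4887 calls (2174 shared), and counts thinned to the smallest library 2149 (2045 shared). Both fits are weak tests, since T288P and T288P+GDF11 hardly differed in mean ribosomal share (10.46% and 10.58%) or mean total (34.72 M each). Whether the correlation comes from a state of the cultures that GDF11 also drives, from 1 unusual well or from its label was not tested.

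An exchange of the labels of M452I replicate 4 and T288P replicate 1 could also place them as seen. On 15 genes chosen without both wells, M452I replicate 4 scored -0.53 on a scale from T288P wells (0) to M452I wells (1), where the other M452I wells scored 0.95 to 1.1, and T288P replicate 1 scored 0.64, where the other T288P wells scored -0.18 to 0.24. So 1 lies beyond every T288P well and the other short of every M452I well. The other M452I wells helped to choose the genes and set the value of 1. A score short of theirs therefore cannot speak against an exchange. WT wells (-0.27 to 0.08) and T288P+GDF11 wells (-0.46 to 0.02) scored much like T288P wells. A low score thus does not mark a well as T288P. The SMPD4BP entry low in M452I stood at 3.47 CPM in M452I replicate 4 and at 8.8 in T288P replicate 1. Each lay near the other wells of its own label (3.39 to 4.95 and 8.63 to 8.87). That entry was the only gene called between the alleles with the labels as given. A match to the labels was thus part of its selection and cannot decide against an exchange. The second entry followed the labels too, with 6.36 CPM in M452I replicate 4 and 0 in T288P replicate 1, a comparison made after these values were seen. With the labels of both wells exchanged edgeR called 4680 genes between M452I and T288P against 1 with the labels as given, so 2 of 35 splits gave as many and chance cannot be excluded for the count. Such a number points to structure among the wells and says nothing of SMPD4BP itself, whose M452I wells (3.39 to 4.95 CPM) lay below the 12 other wells (6.62 to 10.17). An exchange stays open.

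The direct test between the alleles set SMPD4BP apart, with a log2 difference of -1.18 between M452I and T288P (edgeR adjusted p = 0.00513; lower in 4 of 4 wells). Reads shared between 2 entries of that symbol may account for the difference from WT. The sum of both entries was 7.7 ± 1.6 CPM in M452I and 9.02 ± 1.2 in WT, a difference of -1.33 within the spread of 4 wells, because the other entry (ENSG00000152117) stood at 3.83 ± 2.2 against 0.266 ± 0.38. In T288P the sum was 9.32 ± 0.61, and 3 of 4 M452I sums (7.81, 6.14 and 7 CPM) lay below every T288P sum (8.8 to 10.12), while M452I replicate 4 stood at 9.83, so the sum leaves part of the difference between the alleles open. A sequence difference between the lines that moves reads from one entry to the other stays open, as does a difference in transcription.

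For the other comparisons, splits of the 8 wells into 4 and 4 were refitted. In M452I against WT 2 of 35 splits gave at least the 4 real calls, so chance cannot be excluded for the count, and the other 1, which exchanges M452I replicate 4 and WT replicate 4, gave 1132. In T288P against WT 1 of 35 (the real split, 7 genes) gave as many, the highest other being 1. In T288P+GDF11 against T288P it was 1 of 35 (2174, the highest other 1), and in T288P+GDF11 against WT 1 of 35 (4846, the highest other 0 by edgeR). For these 3 counts only the real split gave as many, a share of 0.029. That is the smallest share that 35 splits can give, and it was not adjusted over the comparisons. Every other split mixes wells of both conditions, which widens the shared spread where the conditions differ, so few calls were likely there with GDF11. With 1 line per allele, the splits cannot exclude a chance difference between lines.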

How the results depend on the processing

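The fits without both outlying wells, with the ribosomal covariate, on genes of known length and GC content, with length and GC trends removed and with thinned counts were tests chosen after the data were seen. In the order M452I against WT, T288P against WT, T288P+GDF11 against T288P, M452I against T288P and T288P+GDF11 against WT, edgeR called 4, 7, 2174, 1 and 4846 genes. Counts beyond 1.5 times these came from DESeq2 (28, 80 and, between the alleles, 6), from fits of only the wells compared (0 in M452I against WT, with 899 genes at an unadjusted p under 0.05, and 0 between the alleles, with 240), and from no low-count filter (11 in T288P against WT, 1391 with GDF11 against T288P). Without both outlying wells they were 654, 701 and, between the alleles, 2448. The ribosomal covariate gave 39, 299, 4887 and, against WT, 7512, and removal of length and GC trends 1, 11 and, between the alleles, 0 (364 at an unadjusted p under 0.05). That fit holds 15624 genes, without SMPD4BP, and the same genes without the removal gave 2, 7 and 0 (343), so the 0 comes from the missing gene. A fold of at least 2 gave 2, 2, 410 and, against WT, 1109, by its construction. The replicate number as a block gave 1 in T288P against WT, yet numbers did not pair wells: 4 of 24 correlations exceeded 0.1 (-0.197 to 0.174). Leaving out 1 of the 8 wells compared gave 1 to 9, 1 to 16, 1046 to 2030, 1 to 1 and 3694 to 4541 genes, and a well outside the comparison also counts in the shared model (5006 against WT without T288P replicate 1). Genes shared by both alleles against WT numbered 3, but 20 by DESeq2, 1 with the block, 1 at a fold of at least 2 and 0 to 3 without 1 of the wells compared. Genes opposite between T288P against WT and the GDF11 response numbered 0, but 13 by DESeq2 and 0 to 2 without 1 of the wells compared. The cause was not tested for the other settings.

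Of the log2 fold changes of named genes, 1025 kept direction and side of the threshold without 1 well, 113 no longer passed, 1 newly passed and 21 reversed. With DESeq2 142 kept both and 3 newly passed, with RLE 143 and 2 no longer passed, and with the block 133, with 10 no longer passed (6 of the 7 calls in T288P against WT among them), 1 newly passed and 1 reversed (KRT14 in T288P+GDF11 against WT, 0.01). The reversals were of genes not called. Lowest and highest values without 1 well were, in M452I against WT, GDF11 -0.15 and 0.18, PMEPA1 -0.10 and 0.17, and KRT8 -0.31 and 0.05. In T288P against WT they were -0.15 and 0.18 for GDF11. With GDF11 against T288P, PCSK5 was -0.01 and 0.37. Between the alleles PCSK5 was -0.31 and 0.32, CDH1 -0.03 and 0.06, KRT5 -0.09 and 0.01, and VIM -0.04 and 0.14. In T288P+GDF11 against WT, PCSK5 was -0.26 and 0.02, and KRT14 -0.09 and 0.09. The cause was not tested.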

Other observations

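The relation of PCSK5 to FN1 was a test chosen only after the result was seen.

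With GDF11 against T288P, of 31 glycolysis and hypoxia genes 8 fell, 1 rose and 22 were not called, or 11 and 1 adjusted over the list alone (median log2 fold change -0.248; camera adjusted p = 0.00104; adjusted p = 0.569 with an estimated correlation; fry adjusted p = 0.0902). The glucose transporter SLC2A1 fell from 165 ± 35.2 to 96.1 ± 13.3 CPM and the hexokinases HK2 1.7-fold and HK1 1.46-fold. Of 19 ERK feedback genes 7 fell, 3 rose and 9 were not called, or 8 and 4 passed adjusted over the list alone, and the list did not pass camera (camera adjusted p = 0.165; adjusted p = 0.614 with an estimated correlation), with falls of the receptor EPHA2 (340 ± 59.3 to 178 ± 15.5 CPM) and the EGF receptor ligands HBEGF (67.5 ± 19.1 to 33.6 ± 3.33) and EREG (160 ± 28.7 to 97.5 ± 6.12). Of 17 Notch genes 2 rose and 2 fell, also over the list alone (camera adjusted p = 0.673): the ligand JAG1 rose 1.97-fold and the receptor NOTCH3 fell to a 1.96-fold lower level. Of 23 YAP/TEAD targets 1 rose, the kinase NUAK2 (2.5-fold), and 5 fell, among them LATS2 (1.57-fold lower) and AMOTL2 (1.4-fold lower), or 5 and 6 adjusted over the list alone (camera adjusted p = 0.919).

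Few cell cycle genes were called, and these moved in both directions. Of 33 G2 and mitosis genes 1 rose (HMMR, 2.04-fold) and 3 fell, among them CDC20 (83.1 ± 32 to 33.8 ± 4.16 CPM) and the spindle factor TPX2 (1.37-fold lower), the same adjusted over the list alone (camera adjusted p = 0.52). S phase genes numbered 2 higher and 1 lower of 28, also over the list alone, with a median of 0.041 that turns negative with length and GC trends removed (camera adjusted p = 0.356). Of 25 p53 targets 3 rose and 3 fell, or 5 and 5 adjusted over the list alone, with a median of -0.066 and a camera test towards higher values (camera adjusted p = 0.993). TP53I3 rose 1.51-fold and the stress protein SESN2 fell to a 1.91-fold lower level. Of 26 interferon response genes 1 fell, also over the list alone, with a median of 0.068, a mean of -0.084 and a median below 0 with length and GC trends removed (camera adjusted p = 0.919). Of 2 adipocyte markers 1 fell, too few to test.

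Of 32 nuclear genes of oxidative phosphorylation 2 fell with GDF11 and 30 were not called, also over the list alone, with SDHA from 104 ± 1.88 to 84.7 ± 3.82 CPM (camera adjusted p = 0.00258; adjusted p = 0.71 with an estimated correlation; fry adjusted p = 0.294; camera adjusted p = 0.0654 without T288P replicate 1). Of 13 mitochondrial genome genes 4 fell and 9 were not called, also over the list alone, with MT-ND1 from 1490 ± 132 to 1180 ± 37.4 CPM (camera adjusted p = 0.0413; adjusted p = 0.649 with an estimated correlation; fry adjusted p = 0.096). That list did not pass camera without T288P replicate 2 (0.0888) or 4 (0.257), or T288P+GDF11 replicate 2 (0.0532), 3 (0.0671) or 4 (0.0979). Of 12 histone genes, whose transcripts mostly lack poly(A) tails, 5 fell, or 7 adjusted over the list alone (camera adjusted p = 0.0233; adjusted p = 0.42 with an estimated correlation; fry adjusted p = 0.0255; camera adjusted p = 0.0548 without T288P replicate 3).

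More genes differed between T288P+GDF11 and WT (4846) than between T288P+GDF11 and T288P (2174). A first hypothesis was that wells of T288P vary more than wells of WT. All groups share the estimate of the spread in this model, so a wide spread in T288P enters both tests and does not by itself set them apart. Without T288P replicate 1 the count against T288P was 1046 and that against WT 5006, so removing that well did not close the gap. That fit also leaves fewer wells in the test against T288P, so its count is a weak test of the hypothesis. A second hypothesis was that untreated mutant lines already lie towards the GDF11 response. On the 2174 genes that GDF11 changed in T288P, the M452I wells scored 0.1 log2 units above WT on average (exact p = 0.46 over 70 permutations, n = 4 each) and 1 of 4 lay above all WT wells, against 0.83 for T288P+GDF11. That well was M452I replicate 4 (0.39), while the other 3 scored 0.01, -0.03 and 0.04, inside the range of the WT wells (-0.05 to 0.09). That overlap with WT is what was written beforehand as speaking against the hypothesis for M452I. The T288P wells scored 0.16 above WT on 3558 genes called between T288P+GDF11 and M452I (exact p = 0.14, adjusted 0.28 by Benjamini-Hochberg over both tests; 3 of 4 above all WT wells). T288P replicate 1 scored -0.07 and the other 3 wells 0.26, 0.18 and 0.28. Both averages depend on a well whose label is in doubt, and a shift of T288P stays open.

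The log2 CPM of PCSK5 rose with that of FN1 across the 12 untreated wells (Pearson r = 0.88, permutation p = 0.00037, 0.00074 after Benjamini-Hochberg adjustment over 2 relations; Spearman rho = 0.8, permutation p = 0.0023, adjusted 0.0046). The permutations exchanged wells across the lines. The correlation within groups was 0.88, without a p-value of its own, and that over all 12 wells 0.83 without the 2 farthest, but 2.3% of all genes correlated more strongly with PCSK5 within groups. Among M452I wells both genes were highest in the outlying M452I replicate 4 (66.78 and 98.99 CPM). Whether the relation follows the axis between wells was not tested. In order of axis score, WT replicates 3, 1, 2 and 4 held 57.9, 53.3, 37.3 and 33.1 CPM of PCSK5. T288P replicates 3, 4, 2 and 1 held 56.5, 38.7, 29.4 and 26.4. M452I wells kept the axis order except for replicates 3 and 1 (25.6 and 26.1). FN1 was highest in the well of each line with the highest axis score. A link particular to PCSK5 and FN1 is therefore not shown.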
